A study of Ascodesmis nigricans with 6 samples.

How the data were processed

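RNA sequencing was carried out on 6 libraries of Ascodesmis nigricans strain CBS 389.68, a filamentous ascomycete that forms apothecia, the open fruiting bodies of cup fungi. Per the labels' protocols, cultures grew for 3 days at 25 °C on microscope slides bearing 150 to 200 µl of a rabbit food medium with 0.8% agar, were fixed in ethanol, and RNA was extracted, linearly amplified and sequenced on an Illumina instrument. The protoapothecia, which are young fruiting bodies, are labelled as collected by laser microdissection, whereas the 4 other libraries are labelled as total sexual or total vegetative mycelium. The protocol text is the same for all 6 libraries, so it does not say whether the amplification differed between the mycelium and the microdissected samples. Per the labels, the replicates are independent biological ones, with 2 libraries in each of the 3 groups.

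The deposited table holds raw read counts for 9622 gene models in the 6 libraries, per the file headers, with the mRNA length of each model. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here, nor is whether counting used strand or how reads shared by near-identical genes were treated. The values are whole numbers, and the library totals run from 11589777 to 12835772 counts. The gene models carry protein identifiers with neither a gene name nor a product, and no reference annotation was used here. Genes are therefore given by identifier, positions in the genome are not given, and gene lists by function that had been fixed before the data were examined could not be matched to any gene and were not tested.

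The same table also holds the authors' own comparisons. Per the file headers these are a linear ratio with an adjusted p-value from DESeq, a ratio and a probability from LOX, and a mean ratio from an analysis called "classic" whose method is not given. DESeq is also named in the submitters' processing notes, without a version. The deposited DESeq p-values are rounded to 2 decimals. The deposited DESeq ratios are missing for 68 genes, the number of genes at 0 counts in all 6 libraries. Coded gene classes beside the "classic" ratios were not used because the table does not define the codes.

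Each column of counts was assigned to a library by the title in its name, and no per-sample column was left unused. Genes with too few counts were removed with edgeR's filterByExpr, which kept 8861 genes and left out 761. Library sizes were scaled with trimmed mean of M-values (TMM) factors. All 6 libraries were fitted together by group without a replicate term, since a fit of 2 groups alone would estimate the spread from fewer libraries, and each pair of groups was compared with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust fit, 3 residual degrees of freedom per gene). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Levels are TMM-scaled CPM, the counts relative to the effective library size, as mean ± SD of the 2 libraries. Where all libraries of a group had 0 counts, a lower bound of the fold was set by a floor of 3 counts per library, which equals 0.171 to 0.306 CPM. Other folds of single genes are ratios of pooled scaled counts with a 95% exact (Clopper-Pearson) interval. These floors and intervals cover counting error only, since reads of amplified RNA are not independent molecules. Figures were drawn with matplotlib 3.10.9.

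The genes named were set by a rule written before the data were examined. In each comparison these are the 2 genes with the highest and the 2 with the lowest fitted log2 fold change among those that passed, had a mean of at least 20 counts in the higher group, and had both libraries of one group above both of the other. Genes called in the same direction against both other tissues were counted as above or below both. Because such pairs of comparisons share libraries, the count was set beside the number that independent lists of the same lengths would share and beside 20 simulations of 3 unchanged groups.

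Replicates were checked for duplicate libraries. Chi-square over its degrees of freedom was 51.8 between the vegetative, 114 between the protoapothecia and 272 between the sexual replicates, so every pair differed by more than counting noise. The test was run on simulated counts with 200 changed genes per comparison. This is far fewer than were called in the data. The adjustment is stricter when few genes change, so the shares recovered here do not give the power in the data. The shares recovered are of those changed genes that the filter kept. For a true fold of 8 they were 83.1% in the comparison of protoapothecia with sexual mycelium (8738 genes), 87.5% in that of protoapothecia with vegetative mycelium (8725 genes) and 87.9% in that of sexual with vegetative mycelium (8733 genes). For a fold of 4 the shares were 52.2%, 66.2% and 59.7%, and for a fold of 2 they were 4.6%, 4.5% and 4.5%. Of the calls in these simulations, 8.0%, 8.8% and 6.5% were false. The alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a replicate block, fits of the compared groups alone, leaving out each library, leaving out genes with over 1% of a library, thinning to 1 depth, and a test against a fold of 1.5.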

Results

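Gene expression was measured by RNA sequencing in microdissected protoapothecia of Ascodesmis nigricans, in total sexual mycelium and in total vegetative mycelium, with 2 biological replicates each. The library totals were 11589777 and 12402670 counts for sexual mycelium, 11670664 and 12835772 for vegetative mycelium, and 11794986 and 12676893 for protoapothecia. The sexual libraries had at least 1 count for 9420 and 9373 of the 9622 gene models, the protoapothecia libraries for 9061 and 9021, and the vegetative libraries for 8473 and 8548. The 100 most abundant genes took 40.9% and 41.4% of the counts in vegetative mycelium, 36.4% and 38.1% in protoapothecia, and 34.7% and 27.5% in sexual mycelium.

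Across the 8861 genes tested, the libraries grouped by tissue. Replicates had Pearson correlations of log2 CPM, taken across genes, of 0.984 in vegetative mycelium, 0.961 in protoapothecia and 0.952 in sexual mycelium. Between tissues, the correlations were 0.768 to 0.822 for sexual with vegetative mycelium, 0.562 to 0.583 for protoapothecia with sexual mycelium, and 0.397 to 0.404 for protoapothecia with vegetative mycelium. Genes are not independent replicates, so these values describe the libraries only. Of the 100 most abundant genes of each tissue, protoapothecia shared 31 with vegetative and 23 with sexual mycelium, the mycelia shared 37, and 12 were common to all 3 tissues.

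The comparison of protoapothecia with sexual mycelium asks which transcripts differ between the young fruiting body and total mycelium labelled as sexual. In protoapothecia, 2718 genes were higher and 3267 were lower than in sexual mycelium, and 2876 did not pass. The genes that were higher took 74.4% and 75.7% of the counts in the protoapothecia libraries against 19.7% and 24.0% in the sexual libraries, whereas the genes that were lower took 6.41% and 6.01% against 53.3% and 46.9%. The median fitted log2 fold change was 2.12 among the higher genes and -2.64 among the lower genes, and the fitted fold was 10 or more for 659 higher and 1170 lower genes. Where a tissue had 0 counts, the counts set only a lower bound, so some of the 1170 genes are not shown to differ by a fold of 10. One such gene is proteinId129667, with 31 and 20 counts in the sexual libraries, 0 in protoapothecia and a fitted log2 fold change of -7.31. The number of genes with a mean of at least 20 counts in one tissue and 0 in both libraries of the other was 81 for sexual mycelium and 4 for protoapothecia.

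Of the genes with the highest fold changes in this comparison, proteinId253389, with an mRNA of 462 bases, was at 1564 ± 848 CPM in protoapothecia and 4.83 ± 2.16 CPM in sexual mycelium (SD, n = 2), a 328-fold difference (95% counting interval 280 to 386; edgeR quasi-likelihood adjusted p = 0.000126). Its fitted log2 fold change was 8.34, and 7.67 without protoapothecia replicate 1. The short model proteinId298262 was found only in the protoapothecia libraries, with 36 and 43 counts, which was at least 19.8-fold higher than in sexual mycelium (edgeR adjusted p = 0.00219). In the opposite direction, proteinId342339 had 1 count in each protoapothecia library and 8420 and 6931 counts in the sexual libraries, a 5061-fold lower level (counting interval 1401 to 41792; edgeR adjusted p = 8.08e-05). No count of proteinId311221 was found in protoapothecia, against 907 and 345 counts in the sexual libraries (39.6 ± 28.1 CPM, SD, n = 2; edgeR adjusted p = 0.000518). It was at least 142-fold lower by the mean of the sexual libraries and at least 70.9-fold lower by sexual replicate 2 alone, and its fitted log2 fold change went from -11.94 to -10.86 without sexual replicate 1.

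The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, fitted to all 6 libraries. The balance between higher and lower genes depended on the scaling: higher genes were 45.4% of the calls with TMM factors, 53.1% with RLE size factors (DESeq2's median-of-ratios) and 30.9% with library totals alone. With TMM factors the median log2 fold change over all tested genes was -0.16, with library totals it was -0.78, and with RLE size factors it was 0.15.

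**Figure D1:**
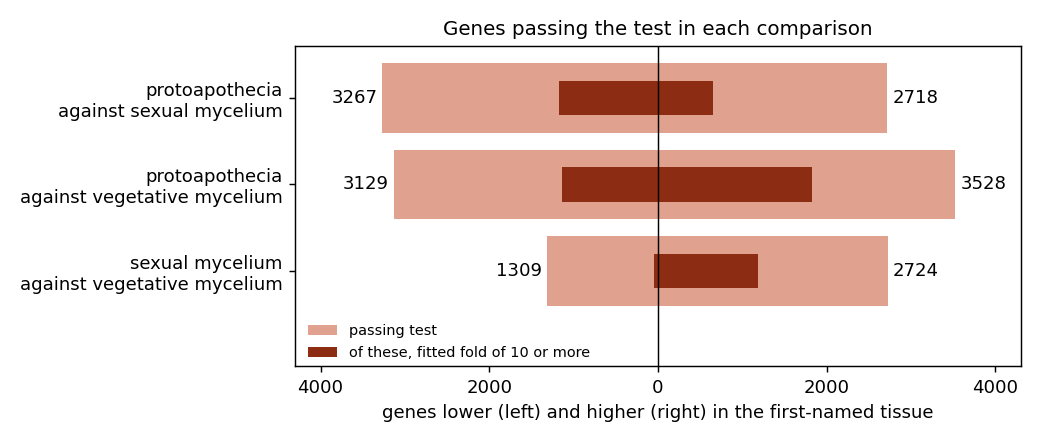
Number of genes passing the edgeR quasi-likelihood test in each comparison (x axis, genes lower to the left and higher to the right of 0 in the first-named tissue), with the darker bars giving those with a fitted fold of 10 or more. The darker bars include genes at 0 counts in a tissue, for which the counts set only a lower bound of the fold. Protoapothecia against vegetative mycelium had the most calls, 3528 higher and 3129 lower, and sexual against vegetative mycelium the fewest, 2724 higher and 1309 lower.

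The comparison of protoapothecia with vegetative mycelium sets the fruiting body against mycelium labelled as vegetative. It gave the most calls of the 3 comparisons: 3528 genes were higher and 3129 were lower in protoapothecia, and 2204 did not pass. The higher genes took 66.8% and 66.9% of the counts in protoapothecia and 8.47% and 8.61% in vegetative mycelium, and the lower genes took 16.66% and 15.96% against 75.1% and 74.9%. The median fitted log2 fold change was 3.47 among the higher and -2.62 among the lower genes. There were 283 genes with a mean of at least 20 counts in protoapothecia and none in vegetative mycelium, and 49 genes with the reverse pattern.

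The most changed of these genes went from abundant in one tissue to at or near 0 in the other. Both proteinId340920, at 1591 ± 153 CPM, and proteinId341996, at 1504 ± 1385 CPM in protoapothecia (SD, n = 2), had no count in vegetative mycelium, and were at least 5379-fold and 5087-fold higher (edgeR adjusted p = 3.15e-05 and 0.000346). The protoapothecia replicates of proteinId341996 differed widely, with 26216 and 5806 counts, and by replicate 2 alone it was at least 1776-fold higher. Its fitted log2 fold change went from 17.19 to 15.73 without protoapothecia replicate 1 and to 17.94 without protoapothecia replicate 2. The gene proteinId342339, also named above, was at 3525 ± 592 CPM in vegetative mycelium (SD, n = 2) and 37935-fold lower in protoapothecia (counting interval 10501 to 313250; edgeR adjusted p = 2.42e-05). A second gene, proteinId344757, was at 151 ± 44.7 CPM in vegetative mycelium (SD, n = 2) and had no count in protoapothecia, at least 543-fold lower (edgeR adjusted p = 3.5e-05). With edgeR and TMM factors 53.0% of the calls were higher, and with upper-quartile factors 47.6%, so which direction held more genes depended on the scaling.

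**Figure D2:**
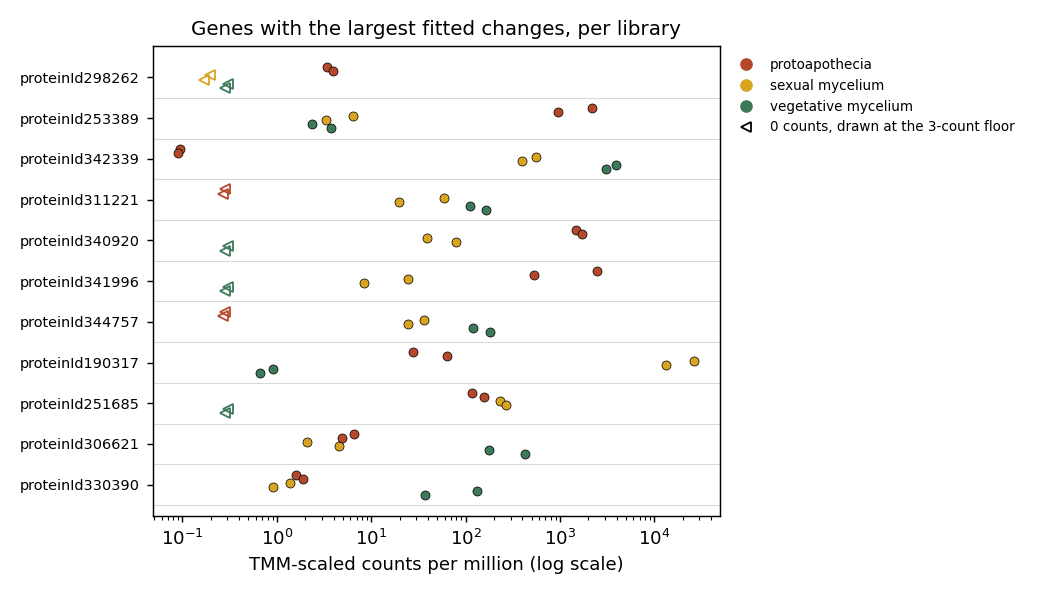
TMM-scaled CPM of each library (x axis, log scale) of the genes with the largest fitted changes in the 3 comparisons (y axis), with circles for single libraries coloured by tissue and open triangles for libraries with 0 counts, drawn at the floor of 3 counts. The vegetative libraries of proteinId330390 had 1289 and 394 counts against 21 and 16 in sexual mycelium, and the protoapothecia libraries of proteinId341996 had 26216 and 5806 counts against 0 in vegetative mycelium.

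Genes called in protoapothecia against both mycelia were counted next. Only the protoapothecia were microdissected, so tissue and collection cannot be told apart in these counts. There were 2306 genes higher in protoapothecia than in both mycelia and 2514 genes lower than in both. Which number was larger depended on the scaling, with 2610 higher and 2271 lower by RLE size factors and 1706 and 2730 by library totals. The 2306 genes took 59.5% and 60.4% of the counts in protoapothecia, 12.3% and 15.7% in sexual mycelium, and 7.33% and 7.30% in vegetative mycelium. The 2514 genes took 4.64% and 4.28% of the counts in protoapothecia, 34.9% and 33.8% in sexual mycelium, and 39.4% and 41.0% in vegetative mycelium. The fitted fold was 10 or more against both mycelia for 623 of the higher and 820 of the lower genes. Some of the 820 genes are not shown to differ by a fold of 10, since 0 counts set only a lower bound. An example is proteinId116632, with 14 and 10 counts in the vegetative libraries, 0 in protoapothecia and a fitted log2 fold change of -6.90 between them. The same limit holds for those of the 623 genes at 0 counts in a mycelium. There were 2 genes with a mean of at least 20 counts in protoapothecia and none in any of the 4 mycelium libraries, and 47 genes with no count in protoapothecia and a mean of at least 20 in both mycelia.

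Independent lists of the same lengths would share 1082 higher and 1154 lower genes, and 20 simulations of unchanged groups gave at most 1 gene in each direction. The unchanged groups gave at most 6 calls against sexual and 5 against vegetative mycelium in a simulation, so this value does not show how far long lists overlap through shared libraries. The 2 comparisons share the protoapothecia libraries, so part of the excess may come from them.

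The comparison of sexual with vegetative mycelium asks how total mycelium labelled as sexual differs from that labelled as vegetative. It gave the fewest calls, with 2724 genes higher and 1309 lower in sexual mycelium, and 4828 that did not pass. The higher genes took 28.9% and 28.7% of the counts in sexual mycelium and 2.53% and 2.98% in vegetative mycelium. The lower genes took 26.6% and 27.7% against 69.0% and 66.8%. Large fitted changes were mostly increases: the fitted fold was 10 or more for 1193 higher and 41 lower genes. Both vegetative libraries were at 0 for 787 of all gene models, where the counts set only a lower bound. An example is proteinId110925, with 9 and 13 counts in the sexual libraries, 0 in the vegetative ones and a fitted log2 fold change of 6.08. Some of the 1193 genes are thus not shown to differ by a fold of 10. There were 224 genes with a mean of at least 20 counts in sexual mycelium and none in vegetative mycelium, and 0 genes with the reverse pattern.

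The gene proteinId190317 was among the 7 and 4 genes that took over 1% of the counts of the sexual libraries. It took 3.49% and 1.90% of all counts in the sexual libraries and had 9 and 7 counts in the vegetative libraries. Its level was 19962 ± 9242 CPM against 0.792 ± 0.178 CPM (SD, n = 2), a 24772-fold difference (counting interval 15254 to 43339; edgeR adjusted p = 0.000364), and it was at 45.5 ± 25.1 CPM in protoapothecia. Its fitted log2 fold change was 14.61, and 14.02 without sexual replicate 1. The gene proteinId251685, at 250 ± 24.7 CPM in sexual mycelium (SD, n = 2), had no count in vegetative mycelium and was at least 844-fold higher (edgeR adjusted p = 0.000324). Of the 2 genes with the lowest fold changes, proteinId306621 was at 3.30 ± 1.70 CPM in sexual and 301 ± 178 CPM in vegetative mycelium (SD, n = 2), 90.2-fold lower (counting interval 74.8 to 110; edgeR adjusted p = 0.000605). The other, proteinId330390, was at 1.14 ± 0.328 CPM against 84.5 ± 66.5 CPM (SD, n = 2), 73.4-fold lower (counting interval 53.0 to 105; edgeR adjusted p = 0.000976). Both values depended on single libraries: the fitted log2 fold change of proteinId306621 went from -6.50 to -5.71 without vegetative replicate 2 and to -7.19 without sexual replicate 2, and that of proteinId330390 from -6.20 to -5.02 without vegetative replicate 1 and to -6.83 without vegetative replicate 2.

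The size and balance of this comparison depended on settings more than those of the others. Without vegetative replicate 1 the count fell from 4033 to 2129 genes and without vegetative replicate 2 to 2421, and higher genes were 67.5% of the calls with TMM factors, 57.5% with RLE size factors and 88.3% with library totals.

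The genes changed against vegetative mycelium were then compared between protoapothecia and sexual mycelium. Of the 2724 genes higher in sexual than in vegetative mycelium, 2057 (75.5%) were also higher in protoapothecia than in vegetative mycelium and 209 were lower. Of the 1309 genes lower in sexual mycelium, 978 (74.7%) were also lower in protoapothecia and 72 were higher. The shared genes were 58.3% of the 3528 genes higher and 31.3% of the 3129 genes lower in protoapothecia. Independent lists would share 1085 higher and 462 lower genes. In 20 simulations of unchanged groups no gene was shared, but these gave at most 5 calls for protoapothecia and 1 for sexual mycelium, which leaves open how far the shared libraries add to long lists. These comparisons share the vegetative libraries, to which part of the excess may belong. The sexual libraries are labelled as total mycelium and may include RNA of protoapothecia, at a share that is not known. Part of the overlap may come from such RNA, so the counts do not by themselves show separate tissues changing alike. All 3 comparisons passed in 1104 genes ordered from protoapothecia over sexual down to vegetative mycelium, and in 516 genes with the reverse order. No comparison passed for 1110 genes by edgeR at an adjusted p under 0.05, and 881 genes had an unadjusted p of 0.05 or more in all 3 comparisons.

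**Figure D3:**
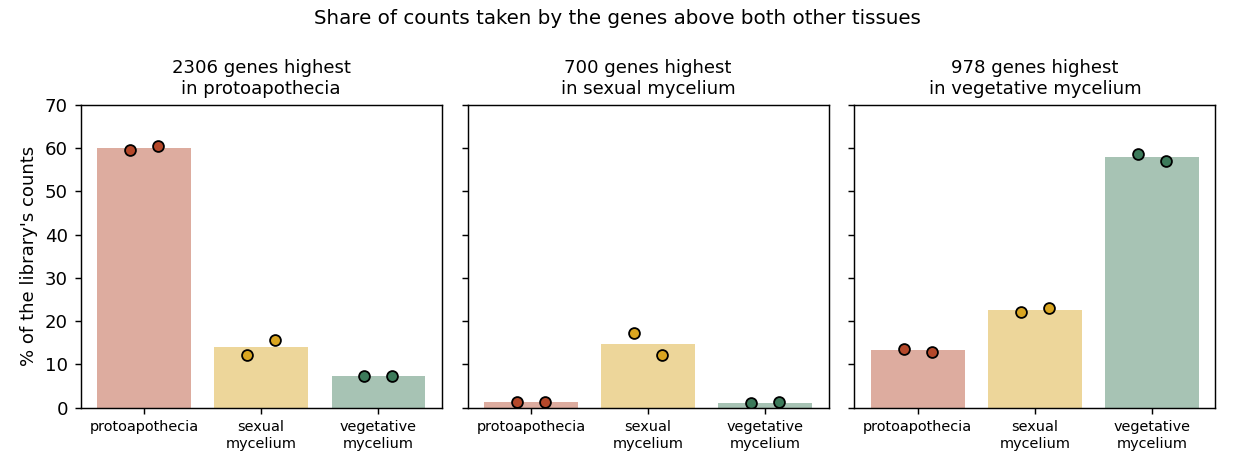
Percent of each library's counts (y axis) taken by the genes called above both other tissues, with points for the 2 libraries of each tissue and bars for their mean. Genes highest in protoapothecia took 59.5% and 60.4% of the protoapothecia counts, and genes highest in sexual mycelium took 17.3% and 12.2% of the sexual counts.

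The authors' deposited table lists 6108 genes with a DESeq adjusted p under 0.05 for protoapothecia against sexual mycelium (3231 higher, 2877 lower), 6810 for protoapothecia against vegetative mycelium (3719 higher, 3091 lower) and 4219 for sexual against vegetative mycelium (2418 higher, 1801 lower). Genes called there and by edgeR here, in the same direction, numbered 5569, 6580 and 3667, and 0 genes were called in opposite directions. Genes called by edgeR alone numbered 416, 77 and 366, and genes called in the authors' deposited table alone 539, 230 and 552. For sexual against vegetative mycelium 546 genes have no deposited DESeq adjusted p, against 68 in each comparison with protoapothecia, and could not be called there. The rounding of the deposited p-values also makes that cutoff stricter than 0.05. Part of the edgeR-only calls may come from these 2 limits. In the authors' deposited table the median ratio of sexual over vegetative mycelium was 1.19 by DESeq, 2.07 by LOX and 2.15 by the "classic" analysis, and that of protoapothecia over vegetative mycelium was 1.2, 1.05 and 1.15. For protoapothecia over sexual mycelium the authors' deposited table has medians on both sides of 1, at 1.1 by DESeq, 0.58 by LOX and 0.61 by the "classic" analysis. These medians cover unlike sets of genes. For sexual over vegetative mycelium the ratio is missing for 68 genes by DESeq, 787 by LOX and 1007 by the "classic" analysis. For protoapothecia over sexual mycelium it is missing for 68, 119 and 305 genes.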

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

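The number of changed genes stayed within 1.5 times its value under all 18 alternatives for protoapothecia against sexual mycelium (5161 to 6136 genes, against 5985), for protoapothecia against vegetative mycelium (5674 to 6762, against 6657), and for the genes above (1706 to 2642, against 2306) and below (2136 to 2881, against 2514) both mycelia. The exceptions were in sexual against vegetative mycelium, where leaving out 1 library gave 2129 to 4276 genes against 4033, the lowest without vegetative replicate 1 and the next, 2421, without vegetative replicate 2; the cause was not tested, and the lone vegetative library is there assumed to vary like the other groups. The vegetative replicates were the closest pair: by log2 CPM, 769 tested genes were over 2-fold apart, against 1484 in protoapothecia and 1175 in sexual mycelium. The shared fit pools these unequal spreads. Protoapothecia and sexual mycelium fitted alone gave 5574 changed genes against 5985. No gene was called in opposite directions by TMM and another of these 18 settings, but the share of higher genes moved with the scaling, as given beside each comparison. Fitting the sexual and vegetative libraries alone gave 56.6% higher genes against 67.5%. Setting their median log2 ratio to 0, added after the data were seen, gave 49.6% of 4013 genes, a balance near even by construction. The 12 named results gave 214 values under the alternatives, all in the same direction. Those genes were picked for their extreme folds in the same libraries, so this outcome was nearly fixed by the choice. In 2 alternatives a named gene was removed from the test. Same-numbered replicates did not deviate together (correlations of deviations from the group means of -0.16, 0.04 and -0.03), and nothing in the labels says that a number marks a shared day. With a replicate block the counts were 5698, 6472 and 3696 genes for the 3 comparisons, and 2192 above and 2426 below both mycelia. The genes that did not pass are not shown to be unchanged, since a test that is not passed does not show equal levels. The self-test recovered few of the changes of a fold of 2, but it changed far fewer genes and does not give the power in the data. Pseudocounts and filters for normalized values were not applied, since the values are counts, and gene list tests could not be run.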

Other observations

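The counts of genes above or below both in sexual mycelium, and the tests of the mixture, the scaling and the carry-over below were chosen after the data were seen; those of the even background, of a few abundant genes and of transcript loss were written before their values were computed. Earlier tests of the mixture (genes above both with library totals) and of carry-over (the 5th percentile of the protoapothecia level, with bounds of 1% and 10% that gave opposite answers) were replaced, since the pattern largely fixed the outcome of the first and a percentile does not stand for the lowest genes.

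By edgeR's quasi-likelihood test, 700 genes were higher in sexual mycelium than in both vegetative mycelium and protoapothecia, with a fitted fold of 10 or more in both for 110 of them. For genes at 0 counts in another tissue the counts set only a lower bound of that fold. Genes with a mean of at least 20 counts in sexual mycelium and none in the 4 other libraries numbered 7, of which 6 were among these calls. The 700 genes took 17.3% and 12.2% of the counts in the sexual libraries, 1.34% and 1.28% in protoapothecia, and 1.07% and 1.36% in vegetative mycelium. The 700 genes were fewer than the 1004 that independent lists of the same lengths would share; unchanged groups shared 0 in 20 simulations, which gave at most 6 and 1 calls in the 2 comparisons. The count fell to 309 and 380 without vegetative replicates 1 and 2 and to 405 without sexual replicate 2, and was 471 with RLE size factors, 447 in a test against a fold of 1.5 and 1934 with library totals. A further 369 genes were lower in sexual mycelium than in both, also fewer than the 402 that independent lists would share (209 and 231 without vegetative replicates 1 and 2, 124 with library totals, 558 with RLE size factors, 624 with DESeq2, 216 in a test against a fold of 1.5). Among 90 genes with at least 1000 counts in both protoapothecia libraries and at most 3 in vegetative mycelium, the level in sexual mycelium was a median of 12.3% of that in protoapothecia (10th to 90th percentile 1.79% to 34.7%).

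One hypothesis is that sexual mycelium is a mixture of vegetative hyphae and protoapothecia with the profiles measured here. The 90 genes above, chosen without regard to the sexual libraries, would then all keep 1 share, but the 90th percentile of their sexual over protoapothecia level was at least 14.2 times the 10th in each of the 4 pairings of libraries, against 4.67 between the sexual and 2.24 between the protoapothecia replicates, so these profiles mixed at 1 share do not account for the sexual libraries. Amplification that differs between the tissues would widen this spread too and remains open. An even background of reads, such as genomic DNA, would by itself give the 700 genes similar read densities. The 90th percentile of sexual reads per kb of mRNA was 30.0 times the 10th, so a background alone does not account for all 700. The genes' own expression widens this spread too, so it cannot show whether a background lifted the weaker ones. Loss of transcripts in the microdissected samples stays open, since microdissection was used in 1 tissue only and the summed excess of the 700 genes over vegetative mycelium, 13.6% of the sexual counts, does not bear on it without a known protoapothecial share; other cells or stages of the sexual mycelium may also carry these transcripts.

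More genes were higher than lower in sexual against vegetative mycelium, 67.5% of the calls with TMM factors. The lowest share over 4 scalings was 57.5% (56.6% when the 2 mycelia were fitted alone), but these all left a median log2 ratio above 0, and setting the median to 0 gives a near even balance by construction (49.6%), so the part of the scaling cannot be told apart from a change in most genes. Fitted folds of 10 or more were mostly increases also with the median at 0 (1012 higher, 97 lower), genes with 0 counts in vegetative mycelium included. A few abundant genes were not the whole cause of the positive median with library totals: it was 1.15, 1.23 without the 15 genes that took over 1% of any library, and 0.92 without the 256 genes among the 100 highest of any library. An even background in the sexual libraries would add the same density to every gene. The 5th percentile of sexual CPM per kb was 0.397, below the median excess of 6.54 over vegetative mycelium, so such a background does not supply the median excess. A smaller background is not excluded by this value, and whether one lifted genes at or near 0 in vegetative mycelium was not tested.

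Among 1229 genes of at least 100 CPM in both vegetative libraries, 949 were present in protoapothecia at over 10% of the vegetative level. Carry-over of RNA with the levels of the vegetative libraries would give every such gene at least the carried-over share. However, 28 of them had a 95% upper counting limit under 1% of the lower vegetative library in both protoapothecia libraries. An even carry-over of 1% or more of such RNA is thus argued against and does not supply levels over 10%. Carry-over from hyphae around the protoapothecia, whose levels may differ from those of vegetative mycelium, was not tested. Loss of these 28 transcripts alone in the protoapothecia samples was not tested.

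Genes lower in protoapothecia had a median mRNA length of 1404 bases against sexual and 1367 bases against vegetative mycelium, and genes higher in protoapothecia 1215 and 1227 bases, while the Spearman correlation of log2 fold change with length across genes, which are not independent replicates, was -0.07 and -0.08.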
